A study of Homo sapiens with 10 samples.

How the data were processed

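RNA-seq was measured in DU145, an established human prostate cancer cell line derived from a brain metastasis, carrying either a control short hairpin RNA (shCon, 3 libraries) or a hairpin against SOX4 (shSOX4, 3 libraries). Another 4 libraries of the series, ATAC-seq of cells with SOX4 overexpression or an empty vector, were not analysed here. Poly-A selected RNA was sequenced as read pairs, per the labels' protocols. The labels describe 2 library kits without saying which library was made with which.

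One deposited table held the values of all 6 RNA-seq libraries. Its column names carry the letters NC and SH with the numbers 1 to 3, and these were read as shCon and shSOX4 with the labels' replicate numbers. The deposited counts are whole numbers per gene, not normalized, per the file headers. The deposited FPKM values are scaled by the authors to gene length and library size, per the file headers. The table also gives the authors' adjusted p-value (false discovery rate) and the authors' log2 fold change for each gene, per the file headers; the tool that made them is not given in the sources used here. The submitters' processing notes name HISAT2, STAR, Bowtie2, MACS2 2.1.1 and deepTools 2.07 for both assays together, without roles, and the build hg19. The counting program, its strand setting, the annotation release and the filter behind the deposited table are not given in the sources used here.

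Several properties of the table bear on the measurements. It holds 13527 features, and every one has a CPM (count scaled to library size) of at least 1 in at least 3 libraries, so genes below that level in both groups had been removed before deposition. Among the features are 1116 loci named newGene, which carry 3.46 to 4.67% of the counts of a library. A single newGene locus is the feature with the most counts in all 6 libraries, with 1.92 to 3.27% of the total. The ratio of count to FPKM should be constant for a gene apart from 1 factor per library, yet it stayed within 5% for only 53.2% of genes, so the deposited counts may be rounded estimates rather than plain tallies. Genes that share sequence with close copies or overlap another gene are therefore uncertain in how their reads were divided. Gene identifiers were matched to current symbols for 12386 features (99.8% of those not named newGene), and 22 symbols that a spreadsheet had turned into dates were restored from the identifier. Biotype and chromosome came from RefSeq's annotation of GRCh38.p14, a newer build than hg19, so no coordinates are given.

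Total counts per library were 43361609, 36360205 and 37012425 for shCon 1, 2 and 3, and 34784541, 31189910 and 34062819 for shSOX4 1, 2 and 3. Group comparisons used edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood F test, two-sided) with group as the only term. The filter removed no feature. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries, and fold changes are shSOX4 relative to shCon on the log2 scale with the standard error (SE) of the fit. Confidence intervals of 95% were taken from that error and the fit's degrees of freedom. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Chi-square values per degree of freedom between libraries of a group were 28.7 to 139, far from duplicates of one library.

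Which genes are named was set before the data were examined. The rule took SOX4 and PCK2, then the 12 largest rises and the 12 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, then up to 4 members of each gene list, those with the smallest adjusted p. A few genes that the rule would name are not reported here, and the next gene in order took the place of each. The 31 gene lists were also fixed then, from textbook knowledge. The 28 lists with at least 5 measured members were tested against all other genes with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members move one way on balance, were run beside it. Each list also has counts of called members adjusted over all genes and adjusted over the list alone.

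Alternatives set before the data were examined were RLE and total-count scaling, no filter, at least 1 CPM in every library of a group, DESeq2 1.42.0, limma-voom, the replicate number as a block, a test against a 1.5-fold change, and leaving out each library in turn. Those added afterwards left out shCon 3 and shSOX4 1 together, left out newGene loci, removed the axis on which those libraries stand apart, used limma on log2(FPKM + 1) with a mean FPKM of at least 1, or used robust dispersions. Fold changes with the axis removed came from limma on log2 CPM with a prior count of 2, so their estimator also differs from edgeR. The main test was tested on simulated data, with counts drawn for the 13527 features and 200 of them changed. It recovered 8.96% of 67 genes changed 1.5-fold, 56.7% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, none in the wrong direction. Of its 123 calls 16 were false (13%), above the nominal 5%, and 12 of these 16 had a simulated dispersion among the highest 10%.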

Results

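The series asks what SOX4, a transcription factor of the SRY-related HMG-box family, does in prostate cancer cells, and whether lowering it holds back neuroendocrine differentiation, the shift of prostate tumour cells to a neuron-like state. RNA-seq of DU145 cells compared 3 libraries with a hairpin against SOX4 (shSOX4) with 3 control libraries (shCon), with 31189910 to 43361609 counts each. The first principal component of log2 CPM held 66.3% of the variance and separated the groups. The second held 15.7% and set shCon 3 (score -29.3) and shSOX4 1 (-35.7) apart from the other 4 libraries, which scored 7.58 to 21.1.

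SOX4 (ENSG00000124766), the targeted gene, was lower in every shSOX4 library than in any shCon library. Its level went from 10.5 ± 2.26 CPM (SD, n = 3) in shCon to 5.67 ± 0.992 CPM (SD, n = 3) in shSOX4, so 53.9% of the transcript remained. It fell by 0.89 on the log2 scale (SE 0.236, adjusted p = 0.0111, edgeR), with a 95% interval from -1.4 to -0.39. Without shCon 1, the library with the highest SOX4, the value was -0.71 and no longer passed (adjusted p = 0.0598, edgeR). PCK2 (ENSG00000100889), the mitochondrial phosphoenolpyruvate carboxykinase that turns oxaloacetate into phosphoenolpyruvate and the second gene in the series title, went from 188 ± 39.6 to 69.9 ± 21.5 CPM (SD, n = 3 each). It fell by 1.43 on the log2 scale (SE 0.223, adjusted p = 0.000375, edgeR), and 37.2% remained. In the authors' deposited table the log2 fold changes of the same genes are -0.83 for SOX4 (adjusted p = 0.00178) and -1.33 for PCK2 (adjusted p = 5.23e-08).

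**Figure D1:**
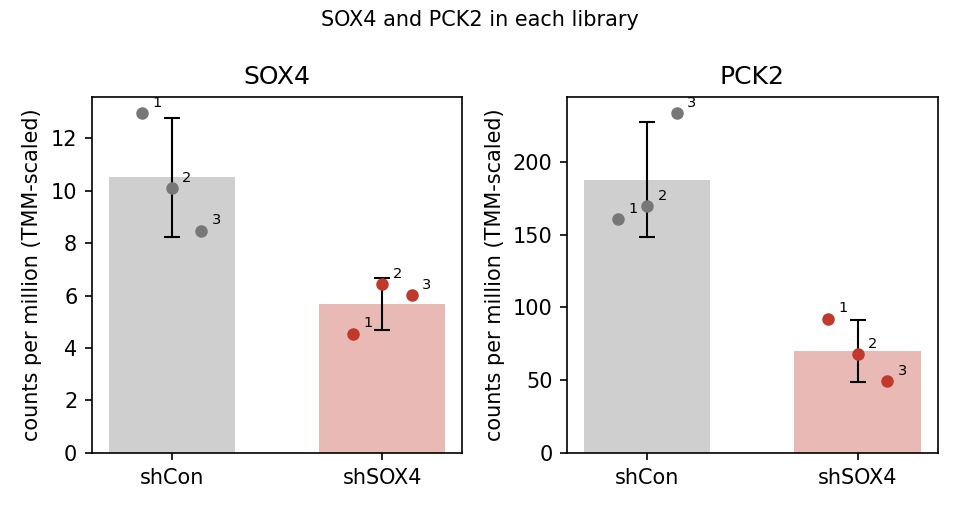
Levels of SOX4 and PCK2 in TMM-scaled CPM (vertical axes) in shCon and shSOX4 cells; bars are means, error bars SD of 3 libraries, and points single libraries with their replicate numbers. All 3 shSOX4 points lie below all 3 shCon points for both genes, with SOX4 between 4.55 and 6.44 CPM in shSOX4 and between 8.48 and 12.9 CPM in shCon.

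Across the transcriptome 4431 of 13527 features changed (32.8%), 2295 upward and 2136 downward. With an absolute log2 fold change of at least 1, 1078 rose and 713 fell. Large changes were mostly rises, with 360 features up and 43 down by at least 2 on the log2 scale, although 97 fell that far without shSOX4 1, 80 without both shCon 3 and shSOX4 1, and with limma on log2(FPKM + 1) 91 rose and 3 fell that far. The 3 values of one group lay wholly above those of the other for 47% of features, where chance gives 10%. Without shSOX4 2 the number changed was 2509, and without both libraries that stand apart on the second component, shCon 3 and shSOX4 1, it was 5532. The authors' deposited table calls 4999 genes, of which 4409 were also called here, every one in the same direction.

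The largest of the 12 largest rises was that of a gene close to silent in control cells. TNNT2, cardiac troponin T, had 11 counts over the 3 shCon libraries and 20.6 ± 5.69 CPM (SD, n = 3) in shSOX4, a log2 fold change of 7.72 (SE 0.496, adjusted p = 1.18e-07, edgeR). With so few control counts its size is uncertain, from 7.17 to 9.03 when 1 library was left out. In the authors' deposited table its log2 fold change is only 3.53, so the size also depends on the method. COL5A1, a fibrillar collagen chain, went from 2.63 ± 0.195 to 88.4 ± 12 CPM, a rise of 5.07 (SE 0.213, adjusted p = 6.9e-09, edgeR). Other genes of the extracellular matrix in this group were FBN2, a fibrillin (4.53), SVEP1 (4.70), the matricellular SPARC, which reached 165 ± 11.5 CPM (3.97), and the secreted glycoprotein FSTL1 (4.09). L1CAM, a neural cell adhesion molecule, rose from 5.29 ± 0.907 to 92.1 ± 10.3 CPM (4.12). The others were OLR1, a receptor for oxidised low-density lipoprotein (4.93), GYPC, which encodes glycophorin C (4.10), PLAC8 (3.99), the kinase gene MAP2K6 (3.92) and FOLR1, a folate receptor (3.89).

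The 12 largest falls were smaller. CBLC, an epithelial ubiquitin ligase, went from 9.66 ± 2.39 to 1.09 ± 0.468 CPM (SD, n = 3 each), a log2 fold change of -3.14 (SE 0.337, adjusted p = 1.23e-05, edgeR). NAPSA, the aspartic protease napsin A, fell by 2.58 and SGPP2, a sphingosine phosphate phosphatase, by 2.41. The cytokine gene IL24 fell by 2.32 and the interleukin-11 receptor gene IL11RA by 2.09. RPS6KA2, a ribosomal S6 kinase of the MAP kinase pathway, went from 80.9 ± 5.28 to 19.6 ± 2.31 CPM and fell by 2.05. BTBD11 fell by 2.11, RAB11FIP4 by 2.11, the carboxypeptidase M gene CPM by 2.08 and MTMR11 by 1.91. TNFRSF6B, a decoy receptor, fell to 23.8% of its control level and HLA-DQB1 fell by 2.03 on the log2 scale, but both are uncertain, since the first overlaps a readthrough transcript from RTEL1 and the second has close relatives.

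**Figure D2:**
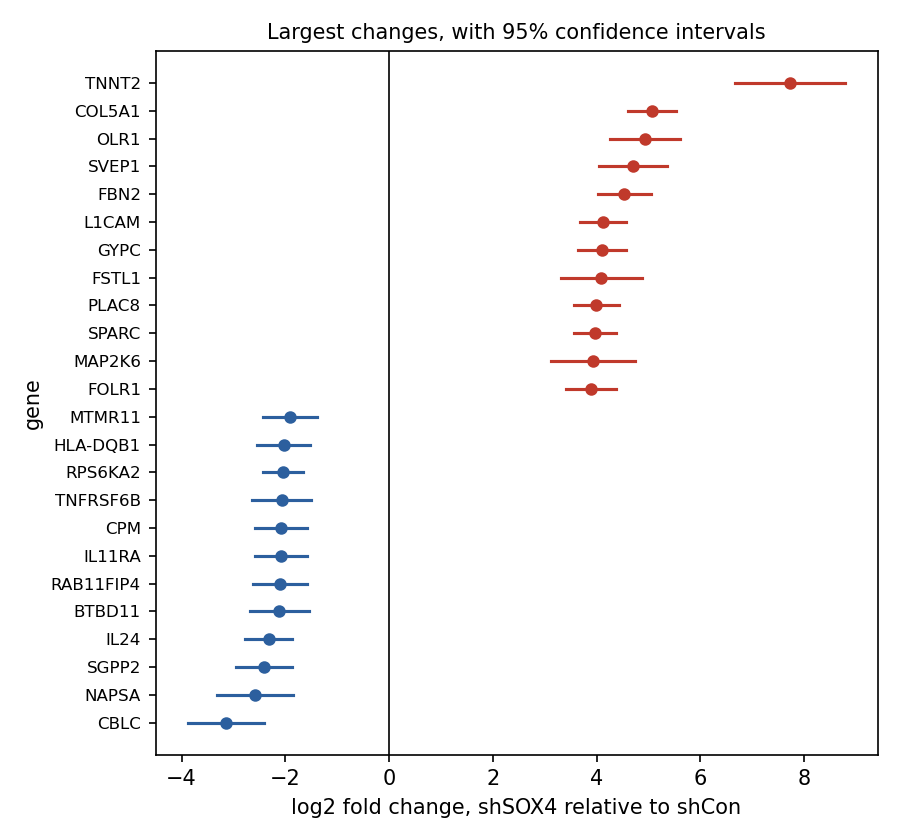
Log2 fold change of shSOX4 relative to shCon (horizontal axis) for the 12 largest rises (red) and 12 largest falls (blue) among the genes that met the naming rule (vertical axis); points are edgeR estimates and lines 95% confidence intervals. The rises run from 3.89 for FOLR1 to 7.72 for TNNT2, and the falls from -1.91 for MTMR11 to -3.14 for CBLC.

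Of 27 neuroendocrine markers only 5 had a row in the table, and 22 of the list were not analysed here. None rose and 2 fell. UCHL1, a neuronal ubiquitin hydrolase, was abundant and went from 1910 ± 170 to 1104 ± 32.2 CPM (SD, n = 3 each), a fall by 0.79 on the log2 scale (SE 0.139, adjusted p = 0.000903, edgeR). SIAH2 fell by 0.50 (adjusted p = 0.0373, edgeR), a call lost in 5 of the 6 fits that left out 1 library. PEG10 had a value of 0.57 (adjusted p = 0.0538, edgeR; 0.0262 by DESeq2), ENO2, neuron-specific enolase, -0.38 (adjusted p = 0.167, edgeR) and DLL3 -0.40 (adjusted p = 0.235, edgeR). Adjusted over the list alone, 1 rose and 2 fell. With 5 members the list did not pass against other genes (camera adjusted p = 0.28). Its median was -0.40, and fry, which asks only whether members move one way on balance, gave a fall (adjusted p = 0.00519). That fry result is not particular to this list. In all 13 lists passed fry, and the luminal markers had the same adjusted p of 0.00519 in the upward direction. Without any single library except shCon 3, 1 marker fell, and 1 rose without shCon 1, without shSOX4 1 or without both shCon 3 and shSOX4 1.

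Markers of luminal prostate cells split, with 6 of 16 up and 4 down (6 and 5 adjusted over the list alone). STEAP4, a metalloreductase, rose from 8.64 ± 2.56 to 110 ± 24.4 CPM (SD, n = 3 each; log2 3.67, adjusted p = 2.1e-07, edgeR). ACPP, prostatic acid phosphatase, rose by 3.24 and the luminal keratin gene KRT8 by 1.33. In shCon, ACPP averaged 0.525 CPM and HOXB13, another counted rise, 0.36 CPM. Both were kept before deposition through their shSOX4 levels and could not have fallen, so the count up is partly fixed by that filter. The list's median was -0.05 while its mean was 0.76, and camera did not call it (adjusted p = 0.489). Without shSOX4 2, and equally without shSOX4 3, 2 luminal markers fell. Among 11 basal markers 2 rose and 3 fell (3 and 5 adjusted over the list alone), with KRT17 up by 2.82 and ITGA6 (-1.08) and KRT15 (-1.18) down (camera adjusted p = 0.664; median -0.02, mean 0.06). Without shCon 1, shCon 2 or shSOX4 2, 1 basal marker rose.

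Genes of epithelial junctions moved both ways, 3 of 17 up and 6 down with either adjustment (3 down without shSOX4 2; camera adjusted p = 0.38). The tight junction gene CLDN4 fell by 1.58 and the polarity gene CRB3 by 1.03, while the desmosomal genes DSP and JUP rose by 1.45 and 1.19. Of 16 mesenchymal genes 7 rose and 1 fell with either adjustment (camera adjusted p = 0.0465, and adjusted p = 0.607 with an estimated correlation). Besides COL5A1 and SPARC, TAGLN, an actin-binding protein of smooth muscle, rose from 28.4 ± 4.49 to 86 ± 3.17 CPM (SD, n = 3 each), and TNC, the matrix protein tenascin C, fell by 1.39. This list's call was lost without shCon 2 (adjusted p = 0.0897), without shSOX4 1 (adjusted p = 0.109), without both shCon 3 and shSOX4 1 (adjusted p = 0.108), without newGene loci (adjusted p = 0.056) and under total-count scaling (adjusted p = 0.0526). It was also lost with limma on log2(FPKM + 1), where 3 of 12 tested members rose and the median was -0.05 against 0.53 (adjusted p = 0.172). TGF-beta targets had 9 of 21 up and 3 down (10 and 4 adjusted over the list alone), with COL4A2 up by 1.36, COL4A1 by 1.25, SKIL by 1.56 and TGFBI by 0.83 (camera adjusted p = 0.0864, but 0.0452 without shSOX4 3 and 0.0127 by DESeq2; adjusted p = 0.51 with an estimated correlation, and 0.621 without shSOX4 3). The number down was 1 without shSOX4 2, 0 without shSOX4 3 and 5 without both shCon 3 and shSOX4 1.

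PCK2 stood among genes of gluconeogenesis, of which 6 of 9 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.167). Without shCon 2, and equally without shSOX4 2, 2 of the 9 fell, and 2 rose without shCon 1, without shSOX4 1 or without both shCon 3 and shSOX4 1. SLC37A4, the glucose-6-phosphate transporter, fell by 0.85 and the aspartate transaminase gene GOT1 by 0.54, a call lost in 2 of the 6 fits that left out 1 library. PC, pyruvate carboxylase, which makes the oxaloacetate that PCK2 uses, rose from 39.4 ± 10.3 to 127 ± 35.2 CPM (SD, n = 3 each; log2 1.68, adjusted p = 0.00012, edgeR). In glycolysis 5 of 20 rose and 4 fell with either adjustment, with the glucose transporter gene SLC2A3 up by 2.94, LDHB up by 0.93 and PFKL down (-0.96) (camera adjusted p = 0.986; median -0.02, mean 0.13). In the tricarboxylic acid cycle 3 of 20 rose and 3 fell with either adjustment, DLD by 0.97 upward (camera adjusted p = 0.995; median -0.04, mean 0.04). Leaving out 1 library also lowered these small counts: in glycolysis 3 rose without shSOX4 3 and 1 fell without shSOX4 2. In the tricarboxylic acid cycle 1 rose without shCon 3, shSOX4 2 or shSOX4 3, and 0 fell without shCon 2, shSOX4 2 or shSOX4 3.

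Genes of serine, glycine and one-carbon metabolism fell, 7 of 17 with none up by either adjustment (camera adjusted p = 0.0249, and adjusted p = 0.51 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, went from 780 ± 146 to 379 ± 61.5 CPM (SD, n = 3 each) and fell by 1.04 on the log2 scale (SE 0.177, adjusted p = 0.000711, edgeR). PSAT1, the next enzyme, fell by 0.79, the mitochondrial serine hydroxymethyltransferase gene SHMT2 by 0.97 and the serine transporter gene SLC1A4 by 1.24. The list's call was lost without shCon 2 (adjusted p = 0.053) and without shSOX4 1 (adjusted p = 0.0509), where 1 member rose, as it did without both shCon 3 and shSOX4 1.

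Of 26 genes on the list of ATF4, the transcription factor of the integrated stress response, and its targets, 15 fell with none up by either adjustment, ATF4 itself among them (camera adjusted p = 0.00186, and adjusted p = 0.51 with an estimated correlation). The number down was 9 without shSOX4 2 and 10 without shCon 2 or shSOX4 3, and the camera call held in each of these fits (adjusted p of 0.00305 to 0.00682). Without shCon 3, 1 member rose, and without both shCon 3 and shSOX4 1, 2 rose. STC2, a secreted glycoprotein, fell by 1.16 (SE 0.153, adjusted p = 8.84e-05, edgeR). NUPR1, a stress-induced nuclear protein, fell by 1.46, VEGFA, the angiogenic growth factor, by 1.01, and the alanyl-tRNA synthetase gene AARS from 1105 ± 134 to 559 ± 79.3 CPM (SD, n = 3 each), a fall by 0.98. The unfolded protein response, a related stress pathway of the endoplasmic reticulum, had 3 of 16 genes up and 3 down with either adjustment (camera adjusted p = 0.947), with ERN1, its sensor kinase, down (-0.98). In cholesterol and fatty acid synthesis 1 of 24 rose and 4 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.28), and the regulators went apart, with SREBF2 down (-1.04) and SREBF1 up (0.94). In this synthesis list 2 fell without shSOX4 2, 1 without shSOX4 3, 7 without shSOX4 1 and 12 without both shCon 3 and shSOX4 1, and 2 rose without shCon 1, shCon 3, shSOX4 1 or shSOX4 3 and 3 without both. In the unfolded protein response 0 rose without shSOX4 2 and 1 without shSOX4 3, and 1 fell without shCon 1, shSOX4 2 or shSOX4 3.

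Immediate-early genes, which answer growth factor signals within minutes, fell in 10 of 21 cases with none up (12 and none adjusted over the list alone; camera adjusted p = 0.00186, and adjusted p = 0.51 with an estimated correlation). DUSP5, a phosphatase that acts on ERK, went from 136 ± 14.2 to 44.9 ± 1.58 CPM (SD, n = 3 each; adjusted p = 7.24e-06, edgeR). Without shCon 1, shSOX4 2 or shSOX4 3, 5 of the 21 fell, and without shCon 1 a single member rose. IER3 fell by 1.16, ZFP36 by 1.33 and JUN by 0.78. Inflammatory genes driven by NF-kB had 8 of 19 down and 1 up (9 and 2 adjusted over the list alone; camera adjusted p = 0.0465, and adjusted p = 0.578 with an estimated correlation). Those that fell included the inhibitor gene NFKBIA, from 323 ± 8.37 to 161 ± 11.1 CPM (SD, n = 3 each), its fellow negative regulator TNFAIP3 (-1.33) and TNFAIP2 (-1.46), and BIRC3, an inhibitor of apoptosis, rose by 1.71. The NF-kB call was lost without shCon 1 (adjusted p = 0.0859), shCon 2 (adjusted p = 0.0552) or shSOX4 3 (adjusted p = 0.0786) and also under total-count scaling (adjusted p = 0.0526) and with limma on log2(FPKM + 1) (adjusted p = 0.105). The number down was 5 without shSOX4 2 or shSOX4 3, and 2 rose without shCon 1.

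Heat shock genes rose, 8 of 15 with none down by either adjustment (camera adjusted p = 0.0105, and adjusted p = 0.51 with an estimated correlation). DNAJA1, a co-chaperone, went from 38 ± 4.04 to 99.7 ± 21.9 CPM (SD, n = 3 each; log2 1.39, adjusted p = 0.000152, edgeR), the chaperone gene HSP90AA1 rose by 1.02, HSPA8 by 1.27 and HSPE1 by 0.89. In the 2 libraries that stand apart, shCon 3 and shSOX4 1, log2 levels less those of the other libraries of the same group had a median of -0.24 over heat shock genes, -0.29 over S-phase genes, -0.20 over G2 and mitosis genes, 0.36 over epithelial junction genes, 0.28 over gluconeogenesis, 0.26 over antigen presentation, 0.24 over glycolysis, 0.23 over the SOX family and 0.22 over mesenchymal genes. It was 0.60 over the leukocyte and 0.21 over the endothelial markers, 2 genes each, and between -0.16 and 0.18 over all other lists.

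**Figure D3:**
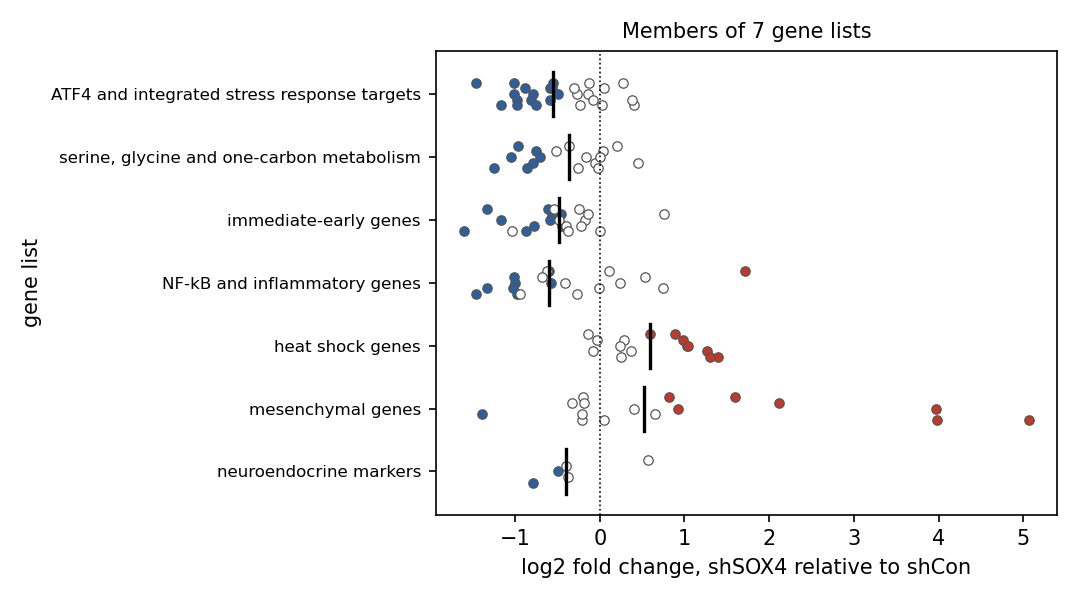
Log2 fold change of shSOX4 relative to shCon (horizontal axis) for the measured members of 7 gene lists (vertical axis, points spread for legibility); filled points passed the edgeR test (red up, blue down), open points did not, and black bars are list medians. The medians are -0.55 for ATF4 and its targets, -0.37 for serine and one-carbon genes, -0.48 for immediate-early genes, -0.60 for NF-kB genes, 0.59 for heat shock genes, 0.53 for mesenchymal genes and -0.40 for the 5 neuroendocrine markers.

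Proliferation genes that changed mostly rose, while the list tests did not pass. Of 32 S-phase genes 9 rose and 1 fell with either adjustment (camera adjusted p = 0.167, and 0.0406 without both shCon 3 and shSOX4 1, where the adjusted p was 0.626 with an estimated correlation), with the ribonucleotide reductase gene RRM1 up by 1.64, BLM by 1.37 and MCM6 by 1.06. Of 36 genes of G2 and mitosis 10 rose and 2 fell with either adjustment (camera adjusted p = 0.0596, but 0.0314 without shCon 1, 0.0262 without shSOX4 1 and 0.0484 by limma-voom), with the kinesin gene CENPE up by 2.13 and ANLN by 0.77. With an estimated correlation the adjusted p for G2 and mitosis was 0.665, and 0.583, 0.632 and 0.632 in those 3 settings. The number down in G2 and mitosis was 0 without shCon 2, shSOX4 1 or shSOX4 2 and 1 without any other single library. In S phase it was 0 without shCon 1, shCon 2, shSOX4 1 or shSOX4 2 and 2 without shCon 3, left out alone or together with shSOX4 1. p53 targets had 7 of 20 up and 3 down (7 and 4 adjusted over the list alone; camera adjusted p = 0.28), with GDF15 up by 2.42, MDM2 up by 0.86 and GADD45A down (-1.05). The number up was 3 without shSOX4 2 and 4 without shCon 1 or shSOX4 3. Interferon-stimulated genes had 9 of 22 up and 3 down (9 and 4 adjusted over the list alone; camera adjusted p = 0.0864, but 0.0465 by DESeq2; adjusted p = 0.51 with an estimated correlation). BST2, tetherin, rose from 32.8 ± 3.74 to 281 ± 32.1 CPM (SD, n = 3 each; log2 3.10, adjusted p = 3.6e-08, edgeR), OASL by 1.15 and OAS1 by 1.65. Antigen presentation had 4 of 15 up and 5 down (4 and 6 adjusted over the list alone; camera adjusted p = 0.57), with HLA-E down (-0.70) and PSMB9 up (0.73). Without shSOX4 2, 5 interferon-stimulated genes rose and 1 fell, and 1 fell without shSOX4 3. Of antigen presentation genes 3 fell without shCon 2, 4 without shSOX4 1 and 2 without any other single library.

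Among the remaining lists, Wnt targets had 1 of 15 up and 5 down with either adjustment (camera adjusted p = 0.108), with AXIN2 down (-1.37) and BMP4 up (0.97). YAP and TEAD targets had 3 of 21 up and 8 down with either adjustment (camera adjusted p = 0.137, but 0.041 with the axis of shCon 3 and shSOX4 1 removed, where the adjusted p was 0.56 with an estimated correlation), with the receptor kinase gene AXL falling from 861 ± 48.2 to 483 ± 35.1 CPM (SD, n = 3 each; log2 -0.83). Hypoxia targets had 3 of 20 up and 5 down with either adjustment (camera adjusted p = 0.535), with ADM up by 1.77 and NDRG1 down (-1.03). In the SOX family SOX4 alone of the 5 measured genes passed (none without shCon 1), and SOX9 had a value of 0.18 (adjusted p = 0.626, edgeR; camera adjusted p = 0.664). Histone genes had 2 of 15 up and 1 down with either adjustment (camera adjusted p = 0.653), the linker histone gene H1F0 being the one that fell (-0.85). Without shSOX4 2 the numbers down were 2 for Wnt, 5 for YAP and TEAD and 2 for hypoxia targets, and 3 fell among both Wnt and hypoxia targets without shCon 2 or shSOX4 3, with 3 Wnt targets down without shCon 1. Without shSOX4 2, 1 hypoxia target rose. The number of histone genes up was 0 without shCon 1 or shSOX4 2 and 1 without shCon 2 or shSOX4 1.

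Markers of cell types other than epithelium were sparse. The 3 measured fibroblast markers of 12 rose, LUM to 2.87 ± 0.753, PDGFRB to 4.20 ± 0.4 and COL1A1 to 6.18 ± 2.26 CPM in shSOX4 (SD, n = 3 each), by 5.02, 2.61 and 2.12 on the log2 scale. The value for LUM ran from 4.52 to 5.77 when 1 library was left out. The 2 endothelial markers of 9 rose, ENG by 3.08 to 22.4 ± 2.77 CPM and CDH5 by 3.01 to 5.88 ± 1.03 CPM. Features had to reach 1 CPM in 3 libraries to be kept before deposition. By the values given, LUM, PDGFRB and CDH5 averaged below that in shCon. They were kept through their shSOX4 levels and could not have fallen. Of 2 leukocyte markers CD68 fell by 1.17 and CD14 had a value of 0.41 (adjusted p = 0.449, edgeR). All these counts are the same when adjusted over the list alone. Features with a symbol of RPL or RPS followed by a digit took 11.5 to 12.1% of the counts in shCon and 12.9 to 14.3% in shSOX4. That set takes in S6 kinase genes such as RPS6KA2 and is not the tested list. The list of ribosomal protein genes had 11 of 37 members up and 3 down with either adjustment (camera adjusted p = 0.137, but 0.00331 with the axis of shCon 3 and shSOX4 1 removed). RPL11 rose by 1.03 and RPS4X by 1.20, genes whose reads can be shared with pseudogenes. With an estimated correlation the adjusted p was 0.742, and 0.605 with the axis removed, a setting that takes away spread between replicates by construction. The number of these up was 5 without shCon 1 or shCon 2, 6 without shSOX4 3 and 7 without shSOX4 1, and the number down was 1 without shCon 2 and 0 without shSOX4 2.

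Mitochondrially encoded genes took 1.07 and 1.1% of the counts in shCon 1 and 2 and 1.83 and 1.78% in shSOX4 2 and 3, while the libraries that stand apart lay between, with 1.55% in shCon 3 and 1.16% in shSOX4 1. Over all 6 libraries 3 of 13 rose (5 adjusted over the list alone) with none down, among them MT-ND5 (0.85) and MT-ND6 (0.86), and the list did not pass (camera adjusted p = 0.0919, but 0.0387 by limma-voom and 0.0377 with limma on log2(FPKM + 1)). Without shCon 3, 10 of 13 rose (camera adjusted p = 0.0051), and without shSOX4 1, 9 rose (camera adjusted p = 0.0201). Without both, 12 rose, with a median log2 fold change of 0.86 against 0.39 over all libraries (camera adjusted p = 0.000113). These genes moved as a unit, with an estimated correlation of 0.95 where camera presets 0.01, and with the estimated correlation the adjusted p was 0.742 over all libraries, 0.698 without shCon 3, 0.666 without shSOX4 1, 0.626 without both, 0.681 by limma-voom and 0.816 on log2(FPKM + 1).

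In all, 6 of the 28 tested lists passed camera with the preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.51 and the smallest unadjusted p were 0.0396 for serine and one-carbon genes and 0.0663 for ATF4 and its targets. By fry 13 lists moved one way on balance.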

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

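The settings added after the data were seen were leaving out shCon 3 and shSOX4 1 together, leaving out newGene loci, removing the axis of those libraries, log2(FPKM + 1), and robust dispersions; all other settings were planned. The number of changed features was 4400 with RLE, 4095 with total-count scaling, 4587 with the stricter filter, 5003 with DESeq2, 4438 with limma-voom, 4607 with robust dispersions and 4101 without newGene loci. Leaving out the filter gave the main result exactly, since the filter removes nothing, so that setting is void. No feature called both there and in the main test changed direction under any setting. Leaving out 1 library in turn gave 2509 (without shSOX4 2) to 4966 (without shSOX4 1) changed features, 1411 to 2653 up and 1098 to 2313 down, and without shSOX4 3 the number down was 1289; fewer libraries lower the power, and no further cause was tested. Falls of at least 2 on the log2 scale numbered 97 without shSOX4 1 and 80 without both libraries that stand apart, against 43, and on log2(FPKM + 1) there were 91 rises and 3 falls of that size against 360 and 43. Against a 1.5-fold change the test passed 1195 features, 782 up and 413 down, 1184 of them with an absolute log2 fold change of at least 1, by its construction. With the axis removed 7477 changed, 3677 up and 3800 down; the removal takes away spread between replicates by construction, so this count overstates the evidence. With limma on log2(FPKM + 1) 632 features had an absolute log2 fold change of at least 1; this setting changes the unit, the added constant, the test and the filter (11287 features tested) together, and which of them lowered the counts was not tested.

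SOX4 was lower in shSOX4 under every setting, from -1.07 with the axis removed to -0.48 on log2(FPKM + 1), and from -1.02 to -0.71 when 1 library was left out. It did not pass without shCon 1 (adjusted p = 0.0598, where the other 5 such fits gave 0.00506 to 0.0331; the cause was not tested), nor against a 1.5-fold change, where its value is -0.89 (adjusted p = 0.208), by construction. PCK2 passed under every setting. For the 137 other named genes and list members, 2321 of 2451 values kept their side of the threshold, 111 lost the call, 19 gained it, and 0 reversed. In 18 of the 131 called genes, SOX4 included, leaving out 1 library ended the call at least once. List calls numbered 3 (without shCon 2) to 7 when 1 library was left out, 0 with an estimated correlation, and 13 by fry, which asks another question; ATF4 and its targets, immediate-early genes and heat shock genes passed in all 16 other fits that could move them, with adjusted p of 0.000301 to 0.00682, 0.000453 to 0.00732 and 0.00185 to 0.0211. Robust dispersions do not enter camera and left every list value as it was, so that setting is void for lists, as is leaving out the filter, and neither is counted. Of 504 list values under the other alternatives, 19 lost a call, 21 gained one and 0 reversed. With an estimated correlation 0 lists passed under any setting where it was run, which excludes DESeq2.

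Replicate numbers did not pair the libraries: deviations from the group means of same-numbered libraries correlated across genes at -0.29, 0.16 and -0.29. With a replicate block 3374 features changed, SOX4 had -0.88 (adjusted p = 0.0175), PCK2 -1.45, and 6 lists passed. At this depth and with 3 libraries a group, 8.96% of 1.5-fold changes were recovered in data simulated with 200 changed features; with the 4431 changed here the adjusted threshold is less strict, so this share does not carry over, and depth and library number were not varied.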

Other observations

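The cancer-testis and collagen lists, the removal of the axis on which shCon 3 and shSOX4 1 stand apart, and the tests of ATF4, fibroblasts and another cell line were chosen after results were seen. The regulators of DNA methylation and the comparison of chromosomes were not among the lists and tests set before the data were examined.

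Cancer-testis genes of the X chromosome, which are silent in most adult tissues outside the germ line, rose in shSOX4 cells, 13 of 15 measured with none down. This count is partly fixed by the filter before deposition, which kept features with at least 1 CPM in at least 3 libraries. XAGE2, all 3 CT45A genes and most GAGE genes averaged under 1 CPM in shCon. They were kept only through their shSOX4 levels and could not have fallen. Genes of these families that were not kept were not analysed here. The list was made after rises of its members were seen, so a list test on it would not be independent evidence. Members of these families have near-identical copies, so single genes are uncertain, and counts were also summed by family. Summed levels went from 10.7 ± 0.719 to 72.3 ± 8.58 CPM (SD, n = 3 each) for 4 MAGEA genes, from 4.06 ± 1.08 to 55.6 ± 10.9 CPM for 4 GAGE genes, and from 0.916 ± 0.167 to 11.3 ± 2.05 CPM for 3 CT45A genes. CSAG1 went from 1.66 ± 0.491 to 19 ± 4.28 CPM. In the XAGE family only XAGE2 passed, from 0.0983 ± 0.048 to 4.68 ± 0.463 CPM, while XAGE1A (0.24, adjusted p = 0.368) and XAGE1B (0.15, adjusted p = 0.563) did not pass by edgeR, and the family's sum had a log2 ratio of 0.38. The list's median log2 fold change was 3.52 by edgeR. With the axis of shCon 3 and shSOX4 1 removed it was 3.32 by limma on log2 CPM with a prior count of 2. The estimator changed too, so the drop cannot be put down to the axis. Collagen genes split, 14 of 24 up and 4 down, a list also made after results were seen. The basement membrane chains COL4A5 and COL4A6 rose by 3.72 and 3.83, COL7A1 of anchoring fibrils by 3.62 and COL12A1 by 2.29, while COL6A2 fell from 104 ± 25.8 to 54 ± 18.5 CPM. Among regulators of DNA methylation, only TET3 passed by edgeR of the 6 measured, rising by 0.94 (adjusted p = 0.00394). The others had values of -0.28 for DNMT1 (adjusted p = 0.174), -0.49 for DNMT3A (adjusted p = 0.0501), -0.41 for UHRF1 (adjusted p = 0.0592), 0.49 for DNMT3B (adjusted p = 0.129) and 0.84 for TET2 (adjusted p = 0.108).

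The real split of the 6 libraries gave 4431 changed features, and the highest of the other splits gave 1. The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05. Every other split also mixes both groups on each side. Any group difference then adds to the spread and keeps calls low, so those counts do not measure false calls.

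PCK2 fell together with genes of the ATF4 and serine lists, none of which is PCK2. With the axis of shCon 3 and shSOX4 1 removed, all 43 measured members of both lists had a median of -0.44, against -0.52 before. The 95% bootstrap interval over members, axis removed, was -0.68 to -0.24. It resampled genes as if they were independent, and not libraries, so it leaves out the spread between libraries. PCK2 had -1.17 with the axis removed (adjusted p = 1.92e-05, limma). Each group holds a library that stands apart, so the removal could move these values only in part. It also takes away spread between replicates, so that p overstates the evidence. Without both libraries the median was -0.52 and PCK2 had -1.49, so the fall did not rest on them. PCK2 had -1.42 with RLE and -1.41 with total-count scaling. The medians were -0.55 for the ATF4 list and -0.36 for the serine list with either scaling. These scalings differ little from each other in these libraries, so swapping them could move such falls only slightly. The values show only that the falls did not rest on this choice. Scaling as a cause stays open, since an error shared by all of these scalings was not tested. A lower activity of ATF4 may link these genes, as a hypothesis: ATF4 itself, a member of its list looked up after its value was seen, fell by 0.50, and 14 of the other 25 members fell, but the list's camera p was 0.0663 with an estimated correlation (0.0602 without ATF4), so a drop of the whole programme relative to other genes stays open. Within each group the library with the least SOX4 had the most PCK2. These were shCon 3, with 8.48 CPM of SOX4 and 233 CPM of PCK2, and shSOX4 1, with 4.55 and 92.2 CPM. Whether SOX4 acts on PCK2 at all, directly or through such a programme, was not tested.

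Large changes were mostly rises, 360 against 43 of at least 2 on the log2 scale, although without shSOX4 1 the numbers were 358 and 97, and on log2(FPKM + 1) 91 and 3. With the axis removed there were still 8.62 rises per fall. Each group holds a library that stands apart on it, so its removal could move such large changes little. Scores on the axis were -0.11, -0.0974 and 0.908 for shCon 1, 2 and 3, and 0.425, -0.513 and -0.613 for shSOX4. The scores were lower on balance in shSOX4, so the removal also altered the group difference itself. Fibroblasts in the shSOX4 cultures would bring their most abundant collagen, yet COL1A1 reached at most 8.31% of COL5A1 in any shSOX4 library. On the other side, the measured fibroblast markers all rose, LUM by 5.02, PDGFRB by 2.61 and COL1A1 itself by 2.12. No fibroblast profile was used here, so this ratio alone does not exclude such cells. Cells of another line, or a subclone of DU145 taken through hairpin selection, could also bring genes that were silent before; if dilution alone lowered genes, the largest fall among protein-coding genes with a mean of at least 5 CPM, -3.14 for CBLC, would need most cells to be of that kind, and no profile of another line was used here, so this cannot be told apart from an effect of SOX4. Effects of the hairpin on genes other than its target were not tested.

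Genes of the X chromosome rose as a group, 115 of 291 with a mean of at least 5 CPM up and 13 down, with a median log2 fold change of 0.45 against -0.02 on 9370 autosomal genes (camera p = 5.59e-10, and p = 0.00073 with an estimated correlation). A few strongly risen genes would leave the lower part of the distribution in place, but the 25th percentile was shifted by 0.433. The median without the cancer-testis families was 0.44. In 10000 random autosomal gene sets the 25th percentile shifted by at most 0.157. Those sets were drawn gene by gene and leave out shifts shared along a chromosome, so their range is too narrow and the camera p may be too small. Whole autosomes moved too, with medians of 0.20 over 423 genes of chromosome 5 and -0.30 over 647 of chromosome 19. Removing the axis left a median shift of 0.433 of 0.473. Along that axis X genes differed by a median of only -0.0279. It could therefore account for little of the shift, and its removal was bound to leave most of it. Autosomal medians ran from -0.30 on chromosome 19 to 0.28 on chromosome 13, while the gene-poor chromosomes 18 and 21 had -0.12 and -0.14, and with the axis removed chromosome 18 was the lowest (-0.28). Base composition stays open, since no genome sequence was used here, and so does a gain of X chromosome copies in the shSOX4 cells, a hypothesis, as copy number was not analysed here.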
